A study of Mus musculus with 20 samples.

How the data were processed

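RNA was sequenced from 20 cultures or samples of the mouse hepatoma line Hepa-1, a liver-derived cell line with an intact aryl hydrocarbon receptor (AHR) response. Cells had been kept in medium with 5% serum and passaged every 3 days, and total RNA was purified on RNeasy columns before Illumina library preparation. The labels place the libraries in 10 groups of 2. At passage 20 there were control-grown cells and cells grown with hexavalent chromium, Cr(VI), and each was treated for 8 hours with the solvent DMSO or with benzo[a]pyrene (B[a]P). At passage 25 there were the same 4 groups and recovered cells, which had 20 passages with Cr(VI) and then 5 without it, again with DMSO or B[a]P. The labels print 0.5 mM for Cr(VI) and 5 mM for B[a]P, while the series title speaks of low concentrations, so these units are given as labelled and were not used in any computation. The sample titles of the later set carry the number 27 where the passage label says 25, and the label was used.

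The deposited file holds raw counts per Entrez gene ID, with 1 column per library, and all 20 columns were matched to the labels. The submitters' processing notes name bcl2fastq, CASAVA 1.8, TopHat, DESeq and the genome build mm10, without saying what each was used for. The program that counted reads, the gene annotation and the strand setting are not given in the sources used here. The table lists 23373 gene IDs, of which 23275 were matched to a symbol and to coordinates in the RefSeq table of GRCm38.p6, the assembly also called mm10. The other 98 IDs kept their numbers, and 47 of them were tested. Transcript length and GC content came from GENCODE M21 and were found for 13482 of the genes tested (94%). Total counts per library were between 20976045 and 37930720, and 3210 gene IDs had no count in any library. Counts that come from reads shared between close paralogs cannot be separated in such a table, which concerns Selenbp1 with Selenbp2, the replication histones, and Ugt1a6a, Ugt1a6b and Ugt1a7c, which share exons.

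Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 14343, libraries were scaled by TMM, and quasi-likelihood negative binomial models with 1 mean per group were fitted to all 20 libraries, with 10 residual degrees of freedom. Each comparison was a contrast of those means, tested two-sided, and p-values were adjusted over the genes tested by the Benjamini-Hochberg method with a threshold of 0.05. Comparisons named for both passages average the effect at passage 20 and at passage 25. Values per library are counts scaled to a common library size (CPM) with TMM-scaled library sizes, group values are means with the SD of 2 libraries, and log2 fold changes carry their standard error (SE). The p-values measure only the spread between these libraries, because the labels do not say whether duplicates came from separate cultures. Passage-25 control libraries served the comparisons of Cr(VI)-grown and of recovered cells alike, so these are not independent of each other. An interaction holds the same DMSO libraries as the comparison of growth histories, with the opposite sign, so these are not independent either. The same is true of the differences between passages and the comparisons that they are made of.

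Whether the replicate numbers pair the libraries was tested by correlating the replicate 2 minus replicate 1 differences of every pair of groups over genes. At passage 25 all 15 correlations lay between 0.81 and 0.92, so the numbers paired those libraries. At passage 20 the 6 correlations lay between 0 and 0.59 with a median of 0.2. The analysis without pairing was kept as planned, and a fit with the replicate number as a block within each passage (replicate block, 8 residual degrees of freedom) is given beside the counts of genes past the threshold, and for lists and named genes where the text says so. Common dispersion was 0.228 without the block and 0.045 with it.

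The fits were tested on counts simulated with the real library sizes, in which 100 genes were changed by 2-fold and 100 by 4-fold. All groups of a passage shared the same simulated difference between replicate numbers, and the spread was that of the block fit. The replicate block was thus true by construction. In the real libraries of passage 20 the correlations of replicate differences were only 0 to 0.59. The shares and false calls with the block may therefore be too favourable for these data. Without the block, 1% of the 2-fold and 48% of the 4-fold changes were recovered for B[a]P in control-grown cells over both passages, and 2% and 29% for Cr(VI). With the block the shares were 70% and 100% for B[a]P and 75% and 98% for Cr(VI), with 5 and 6 false calls. For the interaction of Cr(VI) and B[a]P, for B[a]P at passage 20 and for recovered against control-grown cells, no 4-fold change was recovered without the block, while 94%, 90% and 89% were recovered with it. Counts of 0 in the fit without a block therefore carry little information on changes of this size where few genes change. With few changed genes the adjusted threshold is harder to pass than in a broad response. In the real libraries 177 genes passed for B[a]P at passage 20 without the block, with median log2 values of 2.31 for rises and -2.15 for falls. The shares without the block may thus be too low for a broad response.

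Gene lists of pathways, of cell states and of other cell types were written by hand before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternative settings below. Of 35 lists, 34 had at least 3 measured genes and were tested. The list of mitochondrially encoded genes had 0 measured members. Lists were tested with camera in limma 3.58.1, which asks whether a list ranks higher or lower than the other genes, with a preset correlation between genes of 0.01, and the p-values were adjusted over the 34 lists. Each was repeated with a correlation estimated from the residuals. This estimate and the fry test below came from the fit without the replicate block. Its residuals hold the replicate difference of the passage 25 libraries, which can raise the estimated correlation. Neither was run with the block, so a call lost there does not show that a list was unchanged. Over the 18 comparisons 152 list tests passed with the preset correlation and 34 with an estimated one, all of these in the same direction. Within a list, genes are counted as adjusted over all genes tested and as adjusted over the list alone. The p53 list and the lists of 6 or fewer marker genes for other cell types hold genes that Hepa-1 cells also express.

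Named genes were chosen as follows. Among genes past the threshold with a mean of at least 1 log2 CPM and no overlap of CPM between the groups compared within each passage, the 10 with the largest rise and the 10 with the largest fall were taken. Up to 4 members with the smallest adjusted p were taken from each list described, and Cyp1a1, Cyp1b1, Ahr, Ahrr, Tiparp, Nqo1, Hmox1, Cdkn1a, Mdm2, Mt1, Mt2, Alb and Afp were always reported where measured. Ahrr did not pass the count filter. Where the fit without a block called no gene, the rule was applied to the replicate block, and the text says so.

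The alternative settings fixed then included DESeq2's size factors (RLE), DESeq2 1.42.0 with its Wald test, no count filter, and only the libraries of the groups compared. Another kept only genes past the threshold with at least a 2-fold change, which is a filter and not a test against that change. The others were the replicate block, leaving out each library in turn, camera with an estimated correlation, and the fry test. Fry asks whether a list changed at all and not whether it changed more than the other genes. After seeing the data, the passage 25 library set was added as a batch, alone and with replicate 2 of Cr(VI)-grown DMSO cells at passage 20 not used, as were an offset for transcript length and GC content with the replicate block, and a choice of genes with the replicate block. Tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures with matplotlib 3.10.9. No library was left out of the reported comparisons.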

Results

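The study asked what long-term growth of mouse hepatoma cells with Cr(VI) does to their messenger RNA and to their response to the combustion product B[a]P, a ligand of the AHR whose metabolites bind DNA. RNA-seq counts were compared in 20 Hepa-1 libraries, 2 in each of 10 groups. Control-grown and Cr(VI)-grown cells were sampled at passage 20 and at passage 25, recovered cells at passage 25, and each of these after 8 hours of DMSO or of B[a]P. Total counts per library were 20976045 to 33113295 in the 8 libraries of passage 20. They were 27012268 to 37930720 in replicate 1 and 21795837 to 33070524 in replicate 2 of the 6 groups of passage 25.

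Libraries of passage 25 stood apart by replicate number. On the first principal component, which held 54.2% of the variance, the 6 replicate 2 libraries lay between 80.4 and 106.8 and the 6 replicate 1 libraries between -73.3 and 5.8. In replicate 2 the 100 most counted genes took 29.6% to 34.3% of the counts, against 15.7% to 26.0% in replicate 1, and 14776 to 15329 genes were detected, against 16049 to 17173. At passage 20, replicate 2 of the Cr(VI)-grown DMSO cells differed from replicate 1 by over 2-fold in 32.2% of genes, while the other 3 groups of that passage showed 1.6% to 2.4%. These library differences are given below beside some of the gene groups that moved with them.

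**Figure D1:**
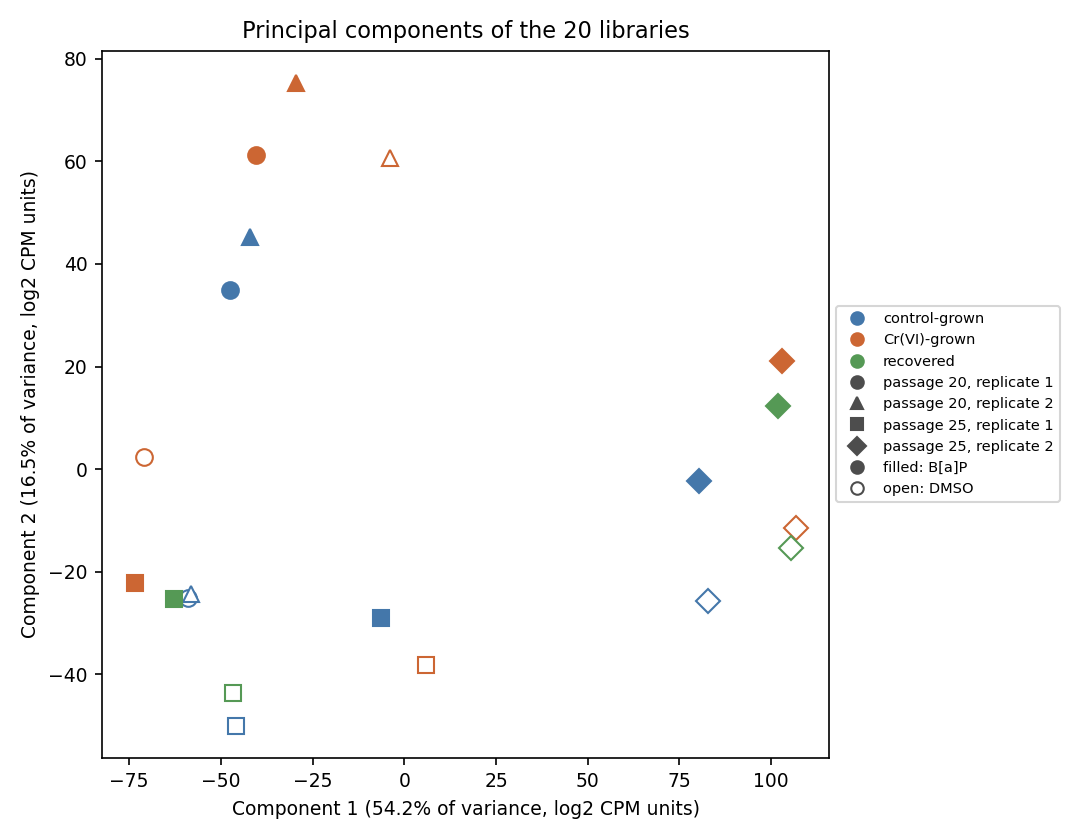
Each point is 1 library, placed by its first (x) and second (y) principal component of log2 CPM, with colour for growth history, shape for passage and replicate number, and filled points for B[a]P. The 6 replicate 2 libraries of passage 25 sit between 80.4 and 106.8 on the x axis, to the right of the other 14 libraries.

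Treatment with B[a]P raised genes of xenobiotic metabolism, oxidative stress and the p53 pathway in control-grown cells. Cyp1a1, which encodes the cytochrome P450 that oxidises aromatic hydrocarbons, rose 37.9-fold over both passages (log2 5.24 ± 0.35 SE, 4 against 4 libraries, adjusted p = 1.13e-05). In the 4 pairs of equal replicate number its log2 difference was 4.97 to 5.93. At passage 20 its mean level went from 37.4 ± 1.1 to 1220 ± 8.3 CPM (SD, n = 2), and at passage 25 from 35.8 ± 7.2 to 1580 ± 420 CPM. Nqo1, a quinone reductase, rose 15.1-fold (log2 3.91 ± 0.24, adjusted p = 6.65e-06), and Hmox1, which encodes the heme-degrading heme oxygenase 1, rose 10.2-fold (log2 3.34 ± 0.40, adjusted p = 0.00138). Of 14343 genes tested, 316 passed, 134 higher and 182 lower, and 1682 had an unadjusted p under 0.05. With the replicate block 2399 passed, which included the 316, and DESeq2 called 766. Without the count filter 178 passed, and with any 1 of the 8 libraries left out between 68 and 150 did.

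The other largest rises included Selenbp1 (28.1-fold) and its paralog Selenbp2 (23.8-fold), whose reads the table may not separate. The cyclin gene Ccno rose 17.4-fold, and with it rose the aldehyde dehydrogenase gene Aldh3a1 (12.9-fold), the alcohol dehydrogenase gene Adh7 (11.2-fold) and Tnfaip2 (7.67-fold). The largest falls were those of the transcription factor genes Sox5 (log2 -4.42 ± 0.55, adjusted p = 0.00173) and Pknox2 (log2 -4.36 ± 0.60, adjusted p = 0.00264), followed by the formin gene Fhod3 (log2 -3.31 ± 0.26, adjusted p = 5.31e-05). After these came Ror1, Cdkal1, Arl15, Arhgap6, the protein kinase C gene Prkce, and the transcription factor genes Foxp1 and Trp63, with log2 values from -3.13 to -2.72. On GRCm38, Cyp1a1 (Entrez ID 13076) lies on chromosome 9 from 57687928 to 57703824 and Nqo1 (ID 18104) on chromosome 8 from 107388225 to 107403205. Hmox1 (ID 15368) lies on chromosome 8 from 75093618 to 75100593 and Sox5 (ID 20678) on chromosome 6 from 143828425 to 144782287. Genes that fell had a median genomic span of 193.1 kb, against 12.1 kb for genes that rose and 20.6 kb for all genes tested.

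**Figure D2:**
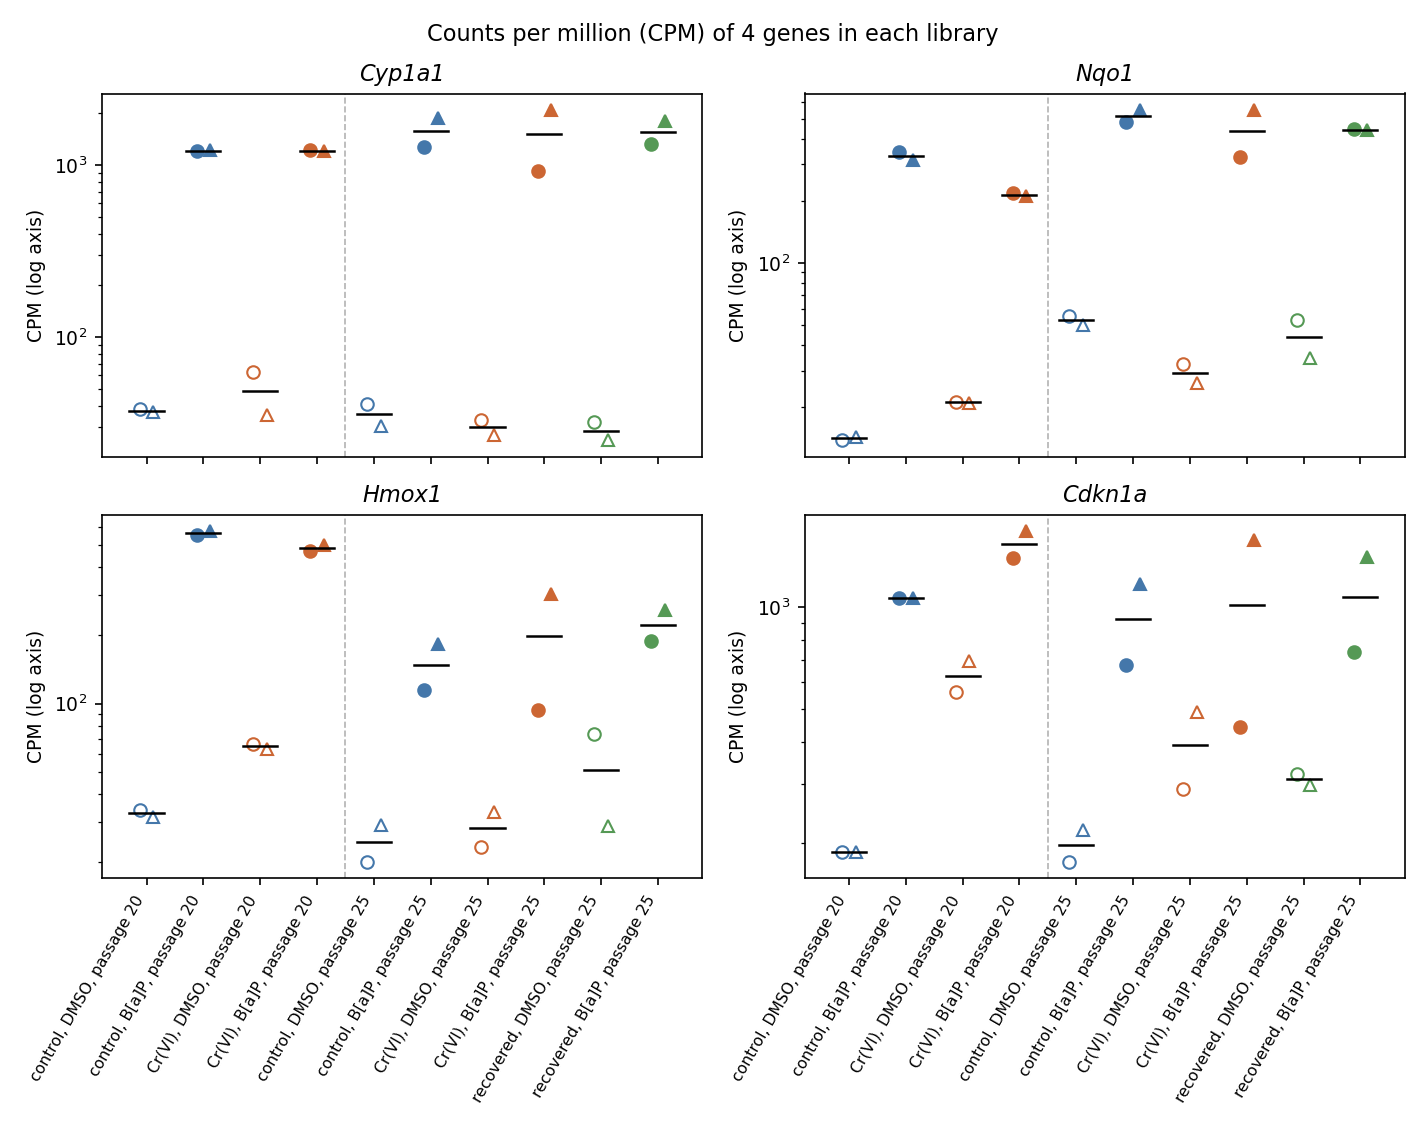
CPM on a log axis (y) of Cyp1a1, Nqo1, Hmox1 and Cdkn1a in each of the 10 groups (x), where circles are replicate 1, triangles replicate 2, filled points B[a]P, black lines the mean of 2 libraries and the dashed line the border between passages. Every B[a]P library lies above the DMSO libraries of its own growth history and passage for Cyp1a1, Nqo1 and Hmox1, while 1 B[a]P library of Cr(VI)-grown cells at passage 25 lies below a DMSO library of its group for Cdkn1a.

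Among the fixed lists, known AHR target genes moved most. Of 16 measured, 7 rose, 0 fell and 9 did not pass, 14 rose when adjusted over the list alone, and the median was 2.03 (camera adjusted p = 5.95e-39, 0.00132 with an estimated correlation). Cyp1a2 (log2 2.63 ± 0.25, adjusted p = 3.93e-04) and the xanthine oxidoreductase gene Xdh (log2 2.01 ± 0.28, adjusted p = 0.00322) were among those that rose. Cyp1b1 (log2 1.87 ± 0.66, adjusted p = 0.224) and Tiparp (log2 2.14 ± 0.78, adjusted p = 0.249) did not pass without the block and passed with it (adjusted p = 7.49e-04 and 4.76e-05). The receptor and its partners had a median of -0.33 in 14 genes and did not pass (adjusted p = 0.235), with 0 members past the threshold over all genes or over the list alone. Ahr itself was at log2 -1.11 ± 0.68 (adjusted p = 0.671, 0.0303 with the block).

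Antioxidant genes of the NRF2 pathway were higher. Of 26, 5 rose, 0 fell and 21 did not pass, 11 rose when adjusted over the list alone, and the median was 0.89 (adjusted p = 8.34e-22, 0.00931 with an estimated correlation), with Srxn1 (log2 2.26 ± 0.30) and Osgin1 (log2 2.42 ± 0.37) beside Nqo1 and Hmox1. Among 30 p53 target genes, 7 rose, 0 fell and 23 did not pass, 13 rose when adjusted over the list alone, and the median was 1.01 (adjusted p = 7.37e-20, 0.00132 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 5.15-fold (log2 2.37 ± 0.39, adjusted p = 0.0075), and the antiproliferative gene Btg2 (log2 2.56 ± 0.25), the death receptor gene Fas (log2 1.17 ± 0.20) and the kinase gene Plk3 (log2 1.99 ± 0.35) rose with it. Mdm2 was at log2 0.91 ± 0.86 (adjusted p = 0.932, 0.0061 with the block). Immediate early genes had 3 rises in 18, 4 rises and 1 fall when adjusted over the list alone, and a median of 0.46 (adjusted p = 6.66e-04, 0.0306 with an estimated correlation), with Dusp1 (log2 0.99 ± 0.19), Fosl1 (2.83-fold) and Jun (log2 1.25 ± 0.28) among them. Conjugating enzymes and transporters had 0 of 21 past the threshold, 1 rise when adjusted over the list alone, and a median of 0.44 (adjusted p = 0.0024, 0.0381 with an estimated correlation).

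Genes of cell division were lower as lists, with no member past the threshold over all genes. The G2 and M phase list had a median of -0.64 in 25 genes (adjusted p = 7.56e-07, 0.0349 with an estimated correlation), with the mitotic genes Bub1b at log2 -0.95 ± 0.28 and Tpx2 at log2 -0.77 ± 0.24. The S phase list had a median of -0.29 in 23 genes (adjusted p = 0.00607), mismatch repair -0.51 in 8 genes (adjusted p = 0.0109), and break and crosslink repair -0.52 in 31 genes (adjusted p = 0.0024). These calls were lost when the correlation was estimated, with adjusted p = 0.176, 0.272 and 0.429 with an estimated correlation in that order. Each of these 4 lists had 0 members past the threshold when adjusted over the list alone. With the replicate block 15, 5, 5 and 12 of their members fell. Base and nucleotide excision repair genes did not pass (median -0.09 in 30 genes, adjusted p = 0.787), although Ung, which encodes uracil-DNA glycosylase, fell by 1.23 ± 0.18 on the log2 scale (adjusted p = 0.00405), the only member past the threshold on either adjustment.

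The ATF4 stress response list had 3 rises in 19 genes and 3 when adjusted over the list alone, Ddit4 (log2 1.75 ± 0.32), Sesn2 (log2 2.04 ± 0.42) and Ppp1r15a (log2 1.24 ± 0.29), with a median of 0.54 (adjusted p = 4.52e-06), and lost its call with adjusted p = 0.272 with an estimated correlation. Endoplasmic reticulum chaperones had a median of 0.26 in 17 genes (adjusted p = 0.0205), PPARA and fat oxidation genes 0.39 in 13 (adjusted p = 0.027) and sterol synthesis genes -0.37 in 21 (adjusted p = 0.0245), with 0 members past the threshold on either adjustment. Their calls were lost with adjusted p = 0.0737, 0.539 and 0.394 with an estimated correlation.

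The remaining lists did not pass for B[a]P in control-grown cells. Their medians and adjusted p were -0.23 and 0.459 for lipogenesis, -0.06 and 0.852 for proteins secreted by hepatocytes and -0.12 and 0.756 for hepatocyte transcription factors and metabolism. They were 0.10 and 0.459 for heat shock, 0.23 and 0.18 for the metal response, 0.10 and 0.18 for hypoxia and glycolysis, and 0.02 and 0.764 for mesenchymal and matrix genes. The values were -0.20 and 0.151 for epithelial adhesion, -0.05 and 0.729 for interferon genes, -0.20 and 0.756 for NF-kB and cytokine genes and -0.24 and 0.519 for chromatin modifiers. Circadian genes had -0.35 and 0.459, with 0.19 and 0.18 for oxidative phosphorylation, 0.12 and 0.567 for ribosomal proteins, and 0.10 and 0.18 for replication histones. For hepatocyte transcription factors and interferon genes the test pointed upward against a negative median, and the heat shock list had a mean of -0.07 against a positive median. Markers of stellate cells and fibroblasts (median -0.23, adjusted p = 0.587), macrophages (0.14, 0.262), endothelium (-0.09, 0.756) and cholangiocytes (-0.35, 0.18) did not pass either. Single members did. The hypoxia list's stress gene Ndrg1 rose (log2 1.78 ± 0.32, adjusted p = 0.0117), as did the RNA sensor gene Ddx58 (log2 0.99 ± 0.24, adjusted p = 0.0491). The lysosomal macrophage marker Cd68 rose (log2 0.88 ± 0.21, adjusted p = 0.049), and the transcription factor gene Sox9, listed for cholangiocytes, fell (log2 -0.88 ± 0.19, adjusted p = 0.0307). Mt1 (log2 0.75 ± 0.55), Alb (log2 -0.06 ± 0.54) and Afp (log2 0.11 ± 0.44) did not pass, and neither did Mt2 (log2 0.89 ± 0.46, adjusted p = 0.535), which passed with the block (adjusted p = 0.0428).

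**Figure D3:**
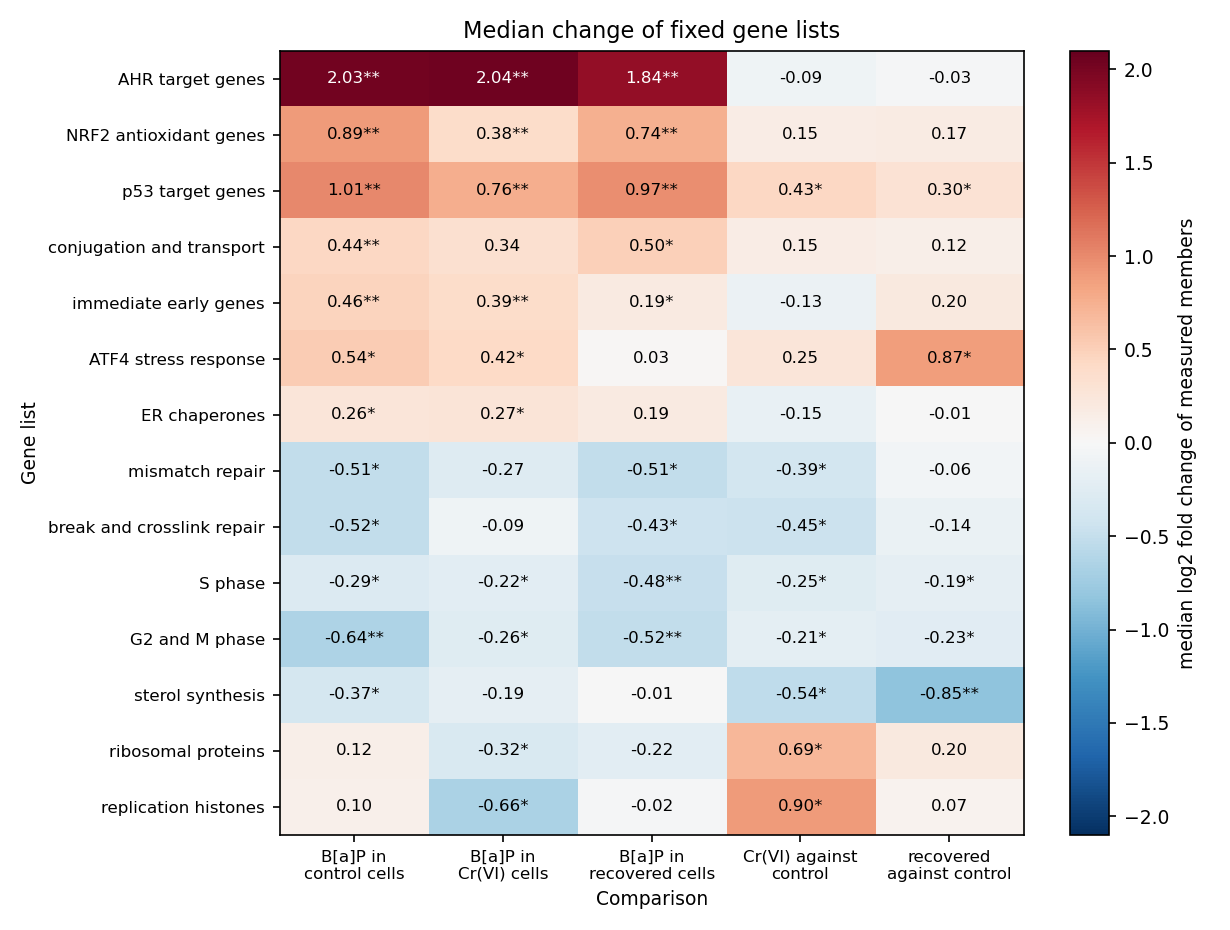
Median log2 fold change of the measured members of 14 fixed gene lists (y) in 5 comparisons (x), in colour and printed, where 1 star marks a list past the camera threshold and 2 stars a list that also passed with an estimated correlation. AHR, NRF2 and p53 target genes carry 2 stars for B[a]P in control-grown, Cr(VI)-grown and recovered cells, and sterol synthesis is the only list shown with 2 stars outside the B[a]P comparisons.

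By passage, 177 genes passed for B[a]P at passage 20 (74 higher, 103 lower) and 7 at passage 25 (6 higher, 1 lower), with 1436 and 545 at an unadjusted p under 0.05. The 7 were Cyp1a1 (44.1-fold), Cyp1a2 (log2 3.70), the cell death gene Bmf (9.96-fold), Tnfaip2 (9.78-fold), Nqo1 (9.75-fold) and the aldehyde oxidase gene Aox3 (5.22-fold), which rose, and Fhod3, which fell by 2.89 on the log2 scale. At passage 20 Cyp1a1 rose 32.6-fold, Ccno 30.4-fold, Nqo1 23.3-fold and Hmox1 17.1-fold, and Tnnc2, Btg2, the growth factor gene Gdf15, Osgin1 and Srxn1 rose between 7.19-fold and 7.95-fold. Sox5, Pknox2 and Fhod3 fell there, with log2 values of -5.30, -4.91 and -3.72. The 74 genes that rose at passage 20 had a median of 1.09 at passage 25, positive for 66 of them, and the 103 that fell had a median of -1.11, negative for 100. Those that fell had a median genomic span of 203.3 kb. Among all genes of 100 to 316 kb 77% were negative at passage 25, and among those over 316 kb 88%, so part of that agreement goes with gene span. Passage 20 and passage 25 share no library, and with genes chosen by the replicate block the median response in the chosen direction at the other passage was 0.60 rather than 1.11. With the replicate block 1917 genes passed at passage 20 and 388 at passage 25. Without 1 library, between 2 and 6 passed at passage 20, the highest without DMSO replicate 1, and between 0 and 5 at passage 25, where the lowest was without DMSO replicate 2.

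The difference of the B[a]P effect between passages, passage 25 minus passage 20 in control-grown cells, had 0 genes past the threshold in edgeR with or without the block, 228 at an unadjusted p under 0.05, and 11 in DESeq2. Nqo1 was at -1.25 ± 0.43 and Hmox1 at -1.50 ± 0.73 on the log2 scale in this difference (adjusted p = 1 for each), while Cyp1a1 was at 0.44 ± 0.59. Genes of the AHR complex were higher in this difference as a list (median 0.86 in 14 genes, adjusted p = 0.0104) and replication histones lower (median -0.55 in 63 genes, adjusted p = 2.13e-06). These calls were lost with adjusted p = 0.349 and 0.42 with an estimated correlation. Both lists also differed between the replicate 2 and replicate 1 libraries of the recovered groups, with medians -1.47 and 1.18 from that of all genes.

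Growth with Cr(VI) was compared with control growth in the DMSO groups. The p53 targets were higher as a list over both passages, with a median of 0.43 and 25 of 30 genes positive (adjusted p = 5.47e-06), and the difference was larger at passage 20, with a median of 0.80 and 27 of 30 positive (adjusted p = 1.43e-06). These calls were lost with adjusted p = 0.207 and 0.12 with an estimated correlation. At passage 25 the p53 list did not pass (median 0.02, 17 of 30 positive, adjusted p = 0.133). In pairs of equal replicate number its median was 0.90 and 0.46 at passage 20 and -0.05 and 0.15 at passage 25. Cdkn1a (Entrez ID 12575, chromosome 17 from 29090979 to 29100722) stood at 188 CPM in control-grown and 627 ± 95 CPM in Cr(VI)-grown cells at passage 20, and at 197 ± 30 and 390 ± 140 CPM at passage 25 (SD, n = 2), which is 2.57-fold over both passages (log2 1.36 ± 0.38, adjusted p = 0.895, 0.0251 with the block). Break and crosslink repair genes, such as the nuclease gene Mre11a (log2 -0.70 ± 0.21) and Fancd2 (log2 -0.79 ± 0.36), were lower as a list, with a median of -0.45 in 31 genes (adjusted p = 1.72e-05, and adjusted p = 0.356 with an estimated correlation). Between the replicate 2 and replicate 1 libraries of the recovered groups this list differed in the same direction, with a median -0.80 from that of all genes. AHR target genes did not pass (median -0.09, adjusted p = 0.453), with Cyp1a1 at log2 0.07 ± 0.30, and neither did NRF2 genes (median 0.15, adjusted p = 0.418) or the metal response (median 0.08, adjusted p = 0.453), with Mt1 at log2 1.04 ± 0.55 and Mt2 at log2 1.23 ± 0.47.

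No gene passed for Cr(VI) in edgeR without a block over both passages, at passage 20 or at passage 25, while 685, 907 and 152 genes had an unadjusted p under 0.05 and DESeq2 called 14, 54 and 0. With the replicate block 531 genes passed over both passages (279 higher, 252 lower), 414 at passage 20 and 0 at passage 25. With the passage 25 library set as a batch, 76 passed over both passages, and with replicate 2 of the Cr(VI)-grown DMSO cells at passage 20 also not used, 0 passed. The named genes below therefore come from the replicate block, with the same sign in each pair of equal replicate number. For the 2 DMSO groups of passage 20 the replicate differences had a correlation of 0, so the numbers do not pair those libraries. The genes below depend on that block and are not established as effects of Cr(VI). The RNA component genes Rmrp (log2 3.40 ± 0.62) and Rpph1 (log2 3.16 ± 0.67) had the largest rises, from low levels of at most 0.141 CPM for Rmrp in control-grown cells of passage 20 to 0.53 and 7.34 CPM in the 2 Cr(VI)-grown libraries. Further rises were those of Akap5, Lrrc17, Azin2, the heme-binding protein gene Hpx, H2-DMa, Golt1a and 1 gene ID without a symbol, with log2 values from 1.48 to 1.87. The largest falls were those of Sox5 (log2 -1.72 ± 0.31), the angiopoietin gene Angpt1 (log2 -1.51 ± 0.31), the protein kinase C gene Prkca (log2 -1.49 ± 0.21) and the formin gene Diaph3 (log2 -1.46 ± 0.31), followed by Slc4a4, Dip2c, Plcb1, Elmo1, Homer1 and Diaph2, from -1.37 to -1.24. Of the p53 targets 8 rose with the block, among them Cdkn1a, Gdf15 (log2 1.29), Bbc3 (log2 0.92) and Dcxr (log2 1.44). With the passage 25 library set as a batch and without the library named above, the adjusted p of Cdkn1a was 0.0536 and that of Mt2 0.171.

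The other lists past the threshold for Cr(VI) over both passages had 0 members past it, adjusted over all genes or over the list alone. Replication histones had a median of 0.90 in 63 genes (adjusted p = 1.83e-11), ribosomal proteins 0.69 in 30 (adjusted p = 5.47e-06) and oxidative phosphorylation 0.43 in 26 (adjusted p = 0.0053). Sterol synthesis had a median of -0.54 in 21 genes (adjusted p = 3.26e-04), lipogenesis -0.45 in 14 (adjusted p = 0.0316), mismatch repair -0.39 in 8 (adjusted p = 0.00758), G2 and M phase -0.21 in 25 (adjusted p = 0.0185) and S phase -0.25 in 23 (adjusted p = 0.0326). All 8 calls were lost when the correlation was estimated: adjusted p = 0.604 for ribosomal proteins, 0.667 for oxidative phosphorylation and 0.356 for the other 6 lists with an estimated correlation. Histones, ribosomal proteins and oxidative phosphorylation were among the lists that differed most between the replicate 2 and replicate 1 libraries of the recovered groups, with medians 1.18, 1.17 and 1.66 above that of all genes. With the passage 25 library set as a batch and without replicate 2 of Cr(VI)-grown DMSO cells at passage 20, ribosomal proteins, oxidative phosphorylation and lipogenesis no longer passed over both passages (adjusted p = 0.0945 for each), and at passage 20 ribosomal proteins (adjusted p = 0.904) and oxidative phosphorylation (adjusted p = 0.935) no longer passed and histones were lower (adjusted p = 0.00657). With all libraries 3 of the 63 histone genes fell at passage 20 when adjusted over the list alone, against a positive median. At passage 25 mismatch repair (median -0.44, adjusted p = 0.0409), break repair (-0.50, 0.00588), sterol synthesis (-0.56, 0.014) and histones (0.91, 9.17e-18) passed, and none of these did with an estimated correlation (adjusted p = 0.497 with an estimated correlation for each). With the replicate block 7 lists passed at passage 25, against 4 without it.

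Whether the Cr(VI) effect itself differed between passages, passage 25 minus passage 20, was also tested. No gene passed in edgeR with or without the block, 303 had an unadjusted p under 0.05, and DESeq2 called 1. The p53 targets were lower in this difference as a list (median -0.61, 5 of 30 positive, adjusted p = 0.00271, and adjusted p = 0.574 with an estimated correlation). Of the 414 genes chosen at passage 20 with the replicate block, the 209 that rose had a median of 0.30 at passage 25 (67.0% positive) and the 205 that fell a median of -0.38 (88.8% negative). In recovered cells against control the medians of these genes were 0.07 and -0.05. Among all genes the share negative for Cr(VI) at passage 25 ran from 36.6% under 10 kb to 77.4% at 100 to 316 kb. The choice of genes also used replicate 2 of the Cr(VI)-grown DMSO cells, which differed from replicate 1 by over 2-fold in 32.2% of genes. These medians therefore do not show that a Cr(VI) effect was kept at passage 25 or lost on recovery.

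In Cr(VI)-grown cells B[a]P again raised AHR, NRF2 and p53 target genes. Cyp1a1 rose 35.4-fold over both passages (log2 5.14 ± 0.35, 4 against 4 libraries, adjusted p = 1.35e-05), from 48.9 ± 19 to 1210 ± 28 CPM at passage 20 and from 30 ± 4.1 to 1510 ± 820 CPM at passage 25 (SD, n = 2). Nqo1 rose 12.3-fold (log2 3.62 ± 0.24, adjusted p = 1.35e-05) and Hmox1 7.27-fold (log2 2.86 ± 0.39, adjusted p = 0.00457). In all, 135 genes passed, 69 higher and 66 lower, with 1278 at an unadjusted p under 0.05, 1620 with the replicate block and 470 in DESeq2. Without the count filter 70 passed, with only the groups compared 2, and with any 1 of the 8 libraries left out between 27 and 90. Of the genes that rose, 62 were among the 134 of control-grown cells (0.645 expected if independent), and of those that fell, 63 were among the 182 (0.837 expected). No gene was called in opposite directions without the block, and 1 was with it. These comparisons share no library, but they share the estimate of each gene's spread. Genes that fell were also long in both, with median spans of 193.1 kb in control-grown and 149.5 kb in Cr(VI)-grown cells, against 20.6 kb for all genes. The counts expected if independent are therefore too low a baseline, and the overlap is a description.

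Further rises in Cr(VI)-grown cells included Selenbp1 (15.7-fold), Selenbp2 (12.4-fold), Adh7 (11.9-fold), Ccno (11.5-fold), Aldh3a1 (8.25-fold) and Tnfaip2 (7.42-fold). Pknox2 had the largest fall (log2 -4.52 ± 0.62, adjusted p = 0.00457), followed by Sox5 (log2 -2.57 ± 0.52), 2210409E12Rik, Arl15, the coactivator gene Ppargc1b, Fhod3, the fibrillin gene Fbn2, Chst8, Fam222a and the cyclin-dependent kinase gene Cdk6 (log2 -2.04 ± 0.27). Of 16 AHR targets 5 rose and 13 when adjusted over the list alone (median 2.04, adjusted p = 3.71e-40, 0.00173 with an estimated correlation). Of 26 NRF2 genes 4 rose and 9 when adjusted over the list alone (median 0.38, adjusted p = 8.72e-15, 0.0293 with an estimated correlation). Of 30 p53 targets 2 rose, Btg2 (log2 2.25 ± 0.25) and the kinase gene Plk2 (2.63-fold), and 9 when adjusted over the list alone (median 0.76, adjusted p = 5.34e-12, 0.00955 with an estimated correlation). Cdkn1a was at log2 1.34 ± 0.38 (adjusted p = 0.152, 0.00448 with the block). Of 18 immediate early genes 2 rose, Dusp1 and Jun, and 5 when adjusted over the list alone (median 0.39, adjusted p = 3.81e-05, 0.0115 with an estimated correlation).

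Other lists past the threshold in this comparison lost their call when the correlation was estimated. G2 and M phase (median -0.26, adjusted p = 9.46e-04) and S phase (-0.22, 0.0362) had adjusted p = 0.122 and 0.296 with an estimated correlation, and the chaperones (0.27, 0.0214) and interferon genes (0.41, 0.0243, with 1 rise in 20, Ddx58, on either adjustment) had 0.0792 each. Epithelial adhesion (-0.51, 0.0231) and the cholangiocyte markers (-0.44, 0.0352, with 1 fall when adjusted over the list alone) had adjusted p = 0.113 and 0.114 with an estimated correlation. Between the replicate 2 and replicate 1 libraries of the recovered groups G2 and M phase, S phase, epithelial adhesion and cholangiocyte markers lay 0.67, 1.02, 0.76 and 0.89 above the median of all genes. The ATF4 list (median 0.42, adjusted p = 0.0359, with 4 rises when adjusted over the list alone) had adjusted p = 0.745 with an estimated correlation and 0.142 with the block. Histones (-0.66, 4.14e-06) and ribosomal proteins (-0.32, 0.0334), which also differed between the replicate sets of passage 25, had adjusted p = 0.578 and 0.815 with an estimated correlation, and 0.481 and 0.406 with the passage 25 library set as a batch and without replicate 2 of the DMSO group at passage 20. By passage, 6 genes passed at passage 20 and 8 at passage 25, against 437 and 782 with the block. Without replicate 2 of the DMSO group 13 genes passed at passage 20, and without replicate 1 none did. The 6 were Cyp1a1 (24.8-fold), Nqo1 (10.1-fold) and Tlcd2 (5.47-fold), which rose, and Hs3st1, Nuak1 and Rasgef1b, which fell (log2 -2.36 for the first and -2.34 for the second). The 8 included Cyp1a1 (50.4-fold), Nqo1 (14.9-fold), Cyp1a2, Bmf, Btg2 and Aox3, which rose, and Fhod3, which fell by 2.67 on the log2 scale.

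The question in the series title, whether Cr(VI) growth altered the response to B[a]P, was tested as an interaction, the B[a]P effect in Cr(VI)-grown minus that in control-grown cells. For the AHR target genes the median difference was -0.11 over both passages and did not pass (adjusted p = 0.11). At passage 20 it was -0.43 and passed (adjusted p = 0.00355), a call lost with adjusted p = 0.441 with an estimated correlation, and at passage 25 it was 0.20 and did not pass (adjusted p = 0.922). For Cyp1a1 it was log2 -0.10 with a 95% confidence interval from -1 to 0.80, and for Nqo1 -0.29 from -0.94 to 0.36. Cdkn1a was at -1.03 from -2.17 to 0.11 and Gdf15 at -1.19 ± 0.58, with adjusted p = 1. NRF2 genes were lower in the difference as a list (median -0.37, 6 of 26 positive, adjusted p = 2.17e-04), as were p53 targets (median -0.23, 11 of 30 positive, adjusted p = 5.36e-05), and break repair genes were higher (median 0.44, 28 of 31 positive, adjusted p = 0.00179). These calls were lost with adjusted p = 0.433, 0.187 and 0.607 with an estimated correlation. Between the replicate 2 and replicate 1 libraries of the recovered groups the medians of the 3 lists lay 0.43, -0.49 and -0.80 from that of all genes. At passage 20 the p53 list had a median of -0.76 with 2 of 30 positive (adjusted p = 9.76e-11) and passed with an estimated correlation as well (adjusted p = 0.0243). Fry, which asks whether the list changed at all, gave an adjusted p of 0.335. The median B[a]P effect on this list in pairs was 1.23 and 1.13 in control-grown and 0.45 and 0.68 in Cr(VI)-grown cells of passage 20. At passage 25 the list did not pass (adjusted p = 0.808, with a median of 0.23 against a test that pointed downward). At passage 20 Cr(VI)-grown cells started from a higher level, as 627 ± 95 against 188 CPM for Cdkn1a, and ended at 1540 ± 200 against 1070 ± 4 CPM after B[a]P (SD, n = 2). Nqo1 was at -1.20 ± 0.43 at passage 20, with levels of 21.1 and 213 ± 4.5 CPM against 14.1 and 329 ± 21 CPM (adjusted p = 1).

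No single gene passed for the interaction in edgeR without or with the block over both passages, at passage 20 or at passage 25, while 60, 67 and 114 had an unadjusted p under 0.05, and DESeq2 called 0 each time. At passage 25 the median over all genes tested was itself 0.20 in this difference, so medians there are read against that value.

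Recovered cells were compared with control-grown cells at passage 25. Genes of sterol synthesis were lower as a list, with a median of -0.85 and 1 of 21 positive (adjusted p = 2e-23, 0.00522 with an estimated correlation). Its members with the smallest p were the sterol demethylase gene Cyp51 (log2 -1.43 ± 0.54), Msmo1 (log2 -1.14 ± 0.50), the squalene epoxidase gene Sqle (log2 -1.12 ± 0.50) and Nsdhl (log2 -1.06 ± 0.44), and 0 passed on either adjustment (adjusted p = 1 over all genes). The ATF4 stress response list was higher, with a median of 0.87 and 19 of 19 positive (adjusted p = 4.4e-22), and missed the threshold with adjusted p = 0.0518 with an estimated correlation. With fry, which asks whether a list changed at all and not against other genes, neither list passed (adjusted p = 0.272 for sterol synthesis and 0.511 for the ATF4 list), nor did any other. The pairs of equal replicate number differed in size. The sterol median was -1.60 in the replicate 1 pair and -0.31 in the replicate 2 pair, and the ATF4 median was 1.34 and 0.13. In the DMSO libraries of recovered cells the ATF4 median of replicate 2 minus replicate 1 was -1.44, while it was 0.64 in control-grown and 0.50 in Cr(VI)-grown cells. Chac1, which encodes a glutathione-degrading enzyme, was at log2 2.44 ± 0.61 (5.44-fold) and was the only member past the threshold when adjusted over the list alone. Sesn2 (log2 1.61 ± 0.58), Mthfd2 (log2 1.60 ± 0.63) and Ppp1r15a (log2 1.14 ± 0.41) had adjusted p = 1 over all genes. The p53 targets (median 0.30, 26 of 30 positive, adjusted p = 4.17e-04), G2 and M phase (-0.23, 3.04e-04), lipogenesis (-0.31, 4.5e-04) and S phase (-0.19, 0.0111) also passed, with 0 members past the threshold on either adjustment. They had adjusted p = 0.144 for p53, G2 and M phase and lipogenesis, and 0.258 for S phase, with an estimated correlation.

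No gene passed for recovered against control-grown cells in edgeR without or with the block, or in DESeq2, and 146 had an unadjusted p under 0.05. Cdkn1a was at log2 0.65 ± 0.53, with 309 ± 15 against 197 ± 30 CPM (SD, n = 2), and Hmox1 at log2 1.05 ± 0.52, with pair differences of 1.86 and -0.01. Against cells still growing with Cr(VI), 0 genes passed in edgeR and DESeq2 and 195 had an unadjusted p under 0.05. There the ATF4 list was higher (median 0.78, adjusted p = 6.34e-09), and sterol synthesis (-0.45, 7.05e-06) and replication histones (-0.70, 2.61e-23) were lower, and the 3 calls were lost with adjusted p = 0.391 with an estimated correlation for each. Since the passage-25 control libraries are shared, the comparisons of Cr(VI)-grown and recovered cells with control are not independent.

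In recovered cells B[a]P raised Cyp1a1 54.9-fold (log2 5.78 ± 0.51, 2 against 2 libraries, adjusted p = 6.34e-04), from 28.5 ± 4.8 to 1560 ± 340 CPM (SD, n = 2), and Nqo1 10.1-fold (log2 3.33 ± 0.33, adjusted p = 0.0011). Bmf (8.57-fold), Cyp1a2 (8.04-fold), Arhgap10 (7.04-fold) and Aox3 (5.79-fold) rose as well, and Fhod3 fell by 2.92 ± 0.36 on the log2 scale (adjusted p = 0.0081). In all, 8 genes passed the threshold, with 526 at an unadjusted p under 0.05, 215 with the replicate block, 103 in DESeq2 and 0 without replicate 2 of the DMSO group. Of 16 AHR targets 3 rose and 11 when adjusted over the list alone (median 1.84, adjusted p = 6.01e-46, 5.4e-04 with an estimated correlation). Of 26 NRF2 genes 1 rose and 6 when adjusted over the list alone (median 0.74, adjusted p = 9.52e-16, 0.019 with an estimated correlation). Of 30 p53 targets 0 rose and 4 when adjusted over the list alone (median 0.97, adjusted p = 1.4e-14, 0.00315 with an estimated correlation). With the replicate block 8, 4 and 6 genes of these 3 lists rose, among them Cyp1b1 (adjusted p = 0.00483), Tiparp (adjusted p = 0.00104), Hmox1 (adjusted p = 0.046) and Cdkn1a (adjusted p = 0.0295). G2 and M phase (median -0.52, adjusted p = 6.95e-09) and S phase (-0.48, 1.48e-06) were lower, each with adjusted p = 0.019 with an estimated correlation and 0 members past the threshold on either adjustment.

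Other lists past the threshold for B[a]P in recovered cells lost the call when the correlation was estimated. Mismatch repair (-0.51, adjusted p = 0.0114) and break repair (-0.43, 0.00145) had adjusted p = 0.245 and 0.431 with an estimated correlation. Interferon genes (0.28, 0.0224), conjugation and transport (0.50, 0.00765) and immediate early genes (0.19, 0.0409) had adjusted p = 0.0646, 0.0595 and 0.14 with an estimated correlation. The 74 genes raised by B[a]P in control-grown cells at passage 20 had a median of 1.30 here, positive for 73, and the 103 lowered ones a median of -1.12, negative for 100. Among all genes spanning 100 to 316 kb 64.3% were negative here, and among those over 316 kb 77.3%. The difference of the B[a]P effect between recovered and control-grown cells had 0 genes past the threshold in edgeR without or with the block and in DESeq2, with 30 at an unadjusted p under 0.05. In it Cyp1a1 was at log2 0.31 ± 0.59 and Nqo1 at 0.05 ± 0.42. The ATF4 list was lower in this difference (median -0.56, 1 of 19 positive, adjusted p = 6.09e-09, and adjusted p = 0.992 with an estimated correlation). It was higher in the DMSO groups of recovered against control-grown cells, and those libraries enter this difference with the opposite sign.

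Genes that fell after B[a]P were long in the genome. In control-grown cells the median log2 fold change over both passages was 0.13 for 4109 genes spanning under 10 kb, 0.06 for 4986 of 10 to 32 kb, -0.15 for 3615 of 32 to 100 kb, -0.54 for 1335 of 100 to 316 kb and -1.12 for 251 over 316 kb. Of the longest class 45 genes fell and 0 rose, and of the shortest 13 fell and 54 rose. The longest class had a negative median in 10 of 10 pairs of B[a]P and DMSO libraries of equal replicate number, from -1.4 to -0.35. For B[a]P it was -0.67 in Cr(VI)-grown and -0.66 in recovered cells. For Cr(VI)-grown against control-grown cells it was -0.92 at passage 20 (-0.61 and -1.28 in the pairs) and -0.26 at passage 25, where it was 0.00 for recovered cells. In replicate 2 minus replicate 1 of the 6 groups of passage 25 it was -0.94 to -0.36.

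**Figure D4:**
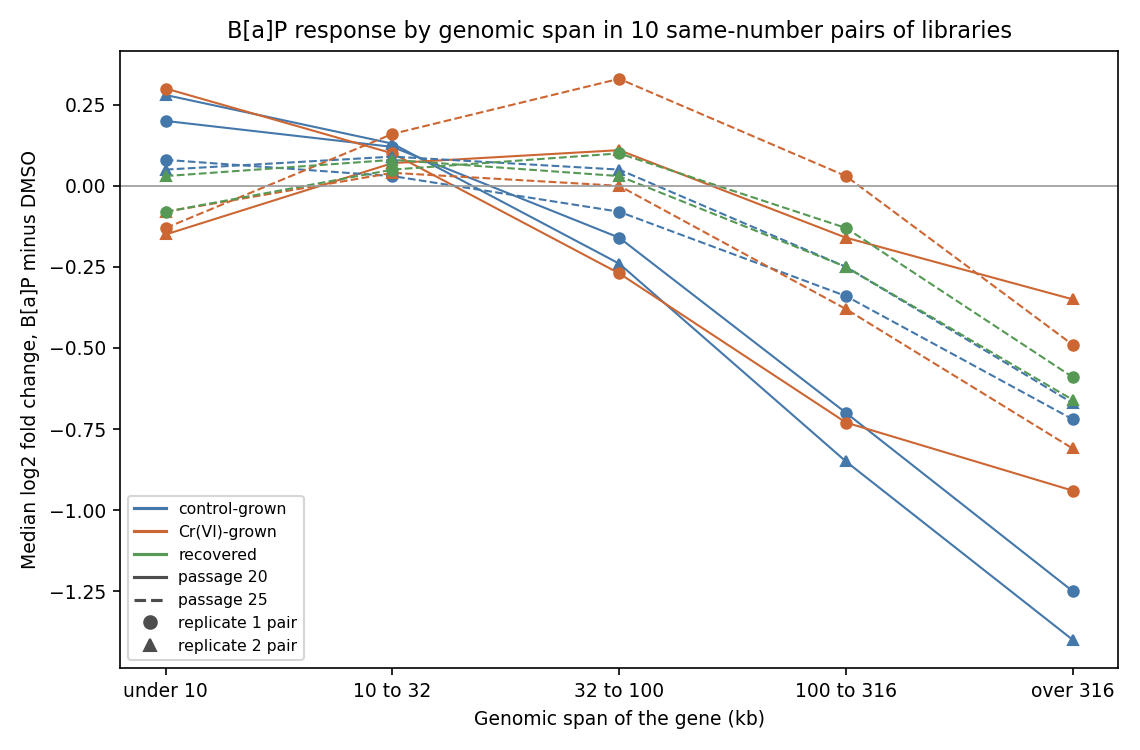
Median log2 difference of B[a]P minus DMSO (y) for genes grouped by genomic span in kb (x), where each line is 1 of 10 pairs of libraries of equal replicate number, with colour for growth history, dashed lines for passage 25 and triangles for replicate 2. In the class over 316 kb every line is below 0, between -1.4 and -0.35.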

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

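The results in this part are gene lists whose response differed between growth histories or passages by a test of the difference itself, and each such test was fixed before the data were examined, while the setting that leaves out 1 library with a batch was chosen after the result was seen. Groups of 2 libraries are too small for a test of single outlying samples. Each interaction holds the DMSO libraries of its comparison of growth histories with the opposite sign, so the results are not independent. This concerns p53 targets, which were higher with Cr(VI) at passage 20, and ATF4 genes, which were higher in recovered cells. The difference of the Cr(VI) effect between passages uses those DMSO libraries again. Values are medians of log2 differences over the list, and 1 of the 42 calls, that of p53 targets at passage 20, also passed with an estimated correlation (adjusted p = 0.0243) while fry, which asks whether a list changed at all and not against other genes, gave an adjusted p of 0.335.

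In the difference of the B[a]P effect between Cr(VI)-grown and control-grown cells over both passages, NRF2 genes stood at -0.37, p53 targets at -0.23, ATF4 genes at -0.39, oxidative phosphorylation at -0.44, ribosomal proteins at -0.46 and replication histones at -0.79. Break and crosslink repair stood at 0.44, G2 and M phase at 0.29, sterol synthesis at 0.41 and interferon genes at 0.39. At passage 20, AHR targets stood at -0.43, NRF2 genes at -0.35, p53 targets at -0.76, ribosomal proteins at -0.42 and histones at -0.80. The AHR complex stood at 0.20 there, G2 and M phase at 0.25, sterol synthesis at 0.22 and interferon genes at 0.26. At passage 25, break repair stood at 0.67, ATF4 genes at -0.36, oxidative phosphorylation at -0.46, ribosomal proteins at -0.42 and histones at -0.71. Between the replicate 2 and replicate 1 libraries of the recovered groups these lists also differed. In the same order they lay -0.80, -0.45, 1.66, 1.17 and 1.18 from the median of all genes, opposite in sign to the interaction except for ATF4 genes. With the replicate block, interferon genes and sterol synthesis over both passages no longer passed (adjusted p = 0.0551 for each). More lists passed by passage with it, 13 against 9 at passage 20 and 8 against 5 at passage 25.

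Without replicate 2 of Cr(VI)-grown DMSO cells at passage 20, and with the passage 25 library set as a batch, the differences of ribosomal proteins (adjusted p = 3.5e-10) and histones (adjusted p = 0.0479) at passage 20 were called in the opposite direction. The AHR complex (adjusted p = 0.907), G2 and M phase (adjusted p = 0.0775) and sterol synthesis (adjusted p = 0.198) no longer passed at passage 20, nor did ribosomal proteins (adjusted p = 0.875) and sterol synthesis (adjusted p = 0.0822) over both passages. The p53 list at passage 20 passed at that setting, in the same direction.

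In the difference of the B[a]P effect between recovered and control-grown cells, sterol synthesis stood at 0.36, fat oxidation at -0.21, ATF4 genes at -0.56 and oxidative phosphorylation at -0.22. In the Cr(VI) effect at passage 25 minus that at passage 20, p53 targets stood at -0.61, ribosomal proteins at -0.59, histones at 0.03 and stellate cell markers at 0.87. The histone call ended with the replicate block (adjusted p = 0.076), and those of ribosomal proteins (adjusted p = 0.0683) and stellate cell markers (adjusted p = 0.319) at the setting with the batch and without that library.

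In the B[a]P effect in control-grown cells at passage 25 minus that at passage 20, the AHR complex stood at 0.86, NRF2 genes at -0.26, p53 targets at -0.34, S phase at -0.46 and lipogenesis at 0.37. Mesenchymal genes stood at 0.36, epithelial adhesion at 0.61, ribosomal proteins at -0.29, histones at -0.55 and cholangiocyte markers at 0.77. The AHR target list did not pass in that difference (adjusted p = 0.0816), with a median of 0.06 against a mean of -0.50.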

How the results depend on the processing

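The settings with the passage 25 library set as a batch, those with an offset and those with genes chosen by the replicate block were added after seeing the data. Counts are of genes past the threshold, and comparisons not named at a setting stayed within 1.5 times their count. Of 120 calls on named genes, all kept their direction and side of the threshold with the replicate block, DESeq2, the batch settings and the offset. Of these calls 26 were lost without the count filter, 60 with only the groups compared and 3 with RLE size factors. The filter for at least a 2-fold change removed 4, which were past the threshold with smaller changes. No named gene that passed in either of the fits compared changed sign, while named genes that passed in neither changed sign 12 times with the block, 32 times with the batch and without the library named below, and 600 times without 1 library. Without 1 library 367 calls on named genes passed and 397 did not. Dispersion fell from 0.228 to 0.045 with the block, and the cause of the other moves was not tested. The spread between duplicates varied widely between groups. Their median absolute log2 difference was 0.076 with DMSO and 0.14 with B[a]P in control-grown cells of passage 20, and 0.6 to 1.2 in the groups of passage 25. The fit to all libraries shares 1 estimate of the spread, while the fit to only the groups compared does not.

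For B[a]P in control-grown cells over both passages, at passage 20 and at passage 25, the counts of 316, 177 and 7 became 2399, 1917 and 388 with the replicate block, 766, 587 and 98 with DESeq2, and 522, 8133 and 0 with only the groups compared. They became 2199, 1688 and 341 with the library set as a batch, 3414, 2908 and 939 with that batch and without replicate 2 of Cr(VI)-grown DMSO cells at passage 20, and 3100, 2482 and 709 with the length and GC offset. Without the filter the counts over both passages and at passage 20 were 178 and 65. For Cr(VI) over both passages and at passage 20, 0 and 0 became 531 and 414 with the block, 14 and 54 with DESeq2, 76 and 146 with the batch, and 393 and 916 with the offset. Without that library and with the batch, 7 passed at passage 20, and at passage 25 10 passed, with 5 at passage 25 with the offset.

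For B[a]P in Cr(VI)-grown cells, 135, 6 and 8 became 1620, 437 and 782 with the block, 470, 157 and 151 with DESeq2, 2, 0 and 0 with only the groups compared, 1501, 390 and 626 with the batch, 2276, 2201 and 2564 without the library as well, and 2978, 807 and 2052 with the offset. Without the filter the first 2 counts were 70 and 2. For B[a]P in recovered cells 8 became 215, 103, 0, 193, 604 and 585 in the same order of settings. The Cr(VI) effect between passages had 1 gene in DESeq2 and 12 with the offset, and the B[a]P effect between passages 11 and 3, with 63 at the setting with the batch and without the library. Of 152 list calls, 34 passed with an estimated correlation and 65 list tests passed with fry. The same direction was called for 34 and 48 of the 152, and for 148 with the block, 152 with RLE, 143 without the filter and 133 with the batch and without that library, where 3 were called in the opposite direction. The median response at the other passage was 1.11 for 177 genes and 0.60 for the 1917 chosen with the block, and the Cr(VI) genes chosen at passage 20 went from 0 to 414.

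With 1 library left out, the lone library of its group is assumed to vary like the other groups. The counts were then 68 (without B[a]P replicate 2 of passage 20) to 150 (without DMSO replicate 1 of passage 25), 2 to 6 and 0 to 5 for B[a]P in control-grown cells. They were 27 (without B[a]P replicate 1 of passage 20) to 90 (without B[a]P replicate 1 of passage 25), 0 to 13 and, at passage 25, 2 (without either DMSO library) to 7 in Cr(VI)-grown cells, and 0 to 5 (without DMSO replicate 1) in recovered cells. For Cr(VI) at passage 20 they were 0 to 97, the highest without replicate 1 of the Cr(VI)-grown DMSO cells, and 0 throughout for the other comparisons.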

Other observations

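In this part the tests of genomic span, of the library sets and of the single library, and the splits that part the pairs, were chosen after the result was seen. Ptgs2, which encodes the prostaglandin-forming enzyme cyclooxygenase 2, rose with the replicate block 9.02-fold after B[a]P in control-grown cells (adjusted p = 3.43e-04) and 10.9-fold in Cr(VI)-grown cells (edgeR adjusted p = 4.44e-04, 4 against 4 libraries each). Cyp2s1, a cytochrome P450 gene, rose 8.07-fold with the block in recovered cells (adjusted p = 1.02e-04), and the keratin gene Krt83 fell after B[a]P in Cr(VI)-grown cells with the block (log2 -3.05 ± 0.61, adjusted p = 0.00588). Without the block, Ndrg1 rose 3.72-fold in Cr(VI)-grown cells (adjusted p = 0.0155), and Adm, which encodes the vessel-relaxing peptide adrenomedullin, rose 11.9-fold (adjusted p = 0.0155) at a level near the limit of detection, with 0 CPM in the control-grown and Cr(VI)-grown DMSO libraries of passage 25 and at most 1.2 CPM in any Cr(VI)-grown library. Both belong to the hypoxia and glycolysis list, which did not pass (adjusted p = 0.309, with a median of -0.12 against a mean of 0.27). In control-grown cells Adm stood at log2 2.54 ± 0.62 (adjusted p = 0.165, 0.0464 with the block).

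In Cr(VI)-grown against control-grown cells, 3 genes of the metal response list rose with the block: the metallothionein gene Mt2 (log2 1.11 ± 0.26, adjusted p = 0.0439), the metal-sensing transcription factor gene Mtf1 (log2 0.59 ± 0.14, adjusted p = 0.0441) and the ferritin gene Ftl1 (log2 1.03 ± 0.27, adjusted p = 0.0496). Without the block each had an adjusted p of 0.895. With the passage 25 library set as a batch and without replicate 2 of Cr(VI)-grown DMSO cells at passage 20, these were 0.171, 0.116 and 0.202.

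After B[a]P the median of 1269 genes over 100 kb minus that of matched genes under 30 kb (872 distinct genes of like transcript length, GC content and level) was -0.6 in control-grown cells over both passages, -0.5 in Cr(VI)-grown and -0.41 in recovered cells. That difference argues against transcript length and GC bias of the libraries as the whole cause. The value at passage 20, -0.87 with -0.81 and -0.89 in its pairs, argues against the passage 25 library sets. Duplicates of the same group also differed in this way. In replicate 2 minus replicate 1 of the passage 25 groups the matched difference was -0.25 to -0.01. In Cr(VI)-grown DMSO cells of passage 20 the long minus short median of log2 CPM was 0.17 in replicate 1 and -0.31 in replicate 2. Other library differences can thus move this value. Assigning B[a]P and DMSO at random within the 5 pairs of groups gave the real difference a two-sided exact permutation p of 0.00026, the smallest that the 7776 assignments allow. The score was built after long genes were seen to be lower in these same libraries, so this p restates that pattern. The assignments also did not keep the pairing of the passage 25 libraries. B[a]P treatment stays a candidate explanation, as a hypothesis found and tested on the same data, and how it would act was not tested. For Cr(VI) growth the difference was -0.47 at passage 20, with -0.30 and -0.72 in its pairs, the larger from the pair with the library doubted below, and -0.14 at passage 25, where it was -0.02 in recovered cells.

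The replicate 2 libraries of passage 25 stood apart from the replicate 1 libraries in the control-grown, Cr(VI)-grown and recovered groups alike. Sequencing depth is argued against by totals that were lower in replicate 2 in 3 of the 6 groups, and an exchange of DMSO and B[a]P libraries by Cyp1a1 levels 14.9 times higher in the lowest B[a]P than in the highest DMSO library. Transcript length and GC content accounted for 43.3% of the variance over genes of the set difference (40.4% to 44.4% by group), between the bounds of 25% and 50% set for the test, so a length and GC bias of the libraries cannot be told apart from other differences between the sets. The nuclear RNA Malat1 was lower in replicate 2 in each group (log2 -5.11 to -2.42) and Gapdh higher (log2 0.98 to 2.35). No biological explanation was tested, since the labels give none for the sets.

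The Cr(VI) calls made with the replicate block depended on library differences, so they do not establish an effect of Cr(VI) on those genes. With the passage 25 library set as a batch 76 genes passed, and 0 passed when replicate 2 of the Cr(VI)-grown DMSO cells at passage 20 was also not used. Over genes, which are not independent replicates, the Cr(VI) log2 fold change followed the set difference of the recovered groups with Spearman's rho of 0.56 (0.55 with the block, 0.30 at passage 20 and 0.69 at passage 25, and 0.34 and -0.35 for B[a]P in control-grown and Cr(VI)-grown cells), and 458 of the 531 called genes (86.3%) had the same sign in both. The p53 list goes against that axis, since its median lay -0.49 from that of all genes in the set difference and 0.46 above it for Cr(VI). It was not alone among the lists called for Cr(VI). Sterol synthesis (0.91 and -0.51), S phase (1.02 and -0.22), G2 and M phase (0.67 and -0.18) and lipogenesis (0.48 and -0.42) went against it too. Histones, ribosomal proteins, oxidative phosphorylation, break repair and mismatch repair went with it. An effect of Cr(VI) on p53 targets stays open as a hypothesis, since its call at passage 20 was lost with adjusted p = 0.12 with an estimated correlation, as was that of the difference between passages (adjusted p = 0.574 with an estimated correlation).

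Other splits of the libraries gave large counts, which points to structure among the samples. For B[a]P in control-grown cells the real split of the 8 libraries called 415 genes with passage as a covariate, and 2 of 34 splits called as many, the real one included. The highest other, at 2008, put the DMSO libraries of passage 20 with both replicate 1 libraries of passage 25. It thus kept the real split at passage 20 and followed the library sets at passage 25. In Cr(VI)-grown cells the real split called 9, 2 of 34 splits called as many, and the highest other, at 1095, parted the libraries by replicate number. Chance was thus not excluded by these counts over all splits. Since the replicate numbers pair the libraries of passage 25, the 12 splits that part both of those pairs were also compared, with the replicate number of passage 25 as a block. The real split called 4336 genes in control-grown and 165 in Cr(VI)-grown cells and the highest other 0 in each, but 12 splits are too few for a share under 0.05. For Cr(VI) itself and for the interaction the real count was 0, so 34 of 34 and 100 of 100 splits called as many by design, which decides nothing on chance, and the highest others called 2919 and 1116.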
